A study of Mus musculus with 2 samples.

How the data were processed

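RNA was measured on 2 Affymetrix mouse expression arrays, 1 of Tbx4-Tm+ and 1 of Tbx4-Tm- cultured lung fibroblasts. Per the labels' protocols, lung fibroblasts from mice with Tbx4-Cre and a tomato reporter were sorted by their fluorescence after passaging, RNA was extracted with Trizol, and cDNA was amplified with an Ovation Pico kit and labelled with biotin. The deposited values were on a log2 scale, as judged from the values: every probe set differed between the arrays by at least 1, the smallest difference being exactly 1, which is 2-fold in base 2. The table had thus been limited to probe sets that differed by 2-fold before it was deposited, and probe sets with smaller differences were not analysed here. All values on both arrays were whole multiples of 0.005 over 11, within 0.001 of a step. Some values recurred across genes and arrays, such as 6.48091 for Nid2 on the Tbx4-Tm- array and for Igfbp3 on the Tbx4-Tm+ array. The processing that gave this step was not identified. The software, the background correction, the normalization and any filter on detection were not given in the sources used here. No detection calls were used, so low values have no known background level.

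Probe sets were named through the array's annotation table, with symbols updated by Entrez identifier from a table of RefSeq mouse genes, used here for names and for which genes neighbour each other. Of the 4144 probe sets, 3529 had 1 gene symbol, 81 several and 534 none, among the latter 21 bacterial control sets, and 3519 of those with 1 symbol matched the reference gene table. Probe sets with several symbols or none named no gene. The value of a gene was the mean of its listed probe sets with exactly 1 symbol, which gave 2639 genes, 633 of them with more than 1 probe set. In 17 genes the listed probe sets differed in opposite directions. Between probe sets of one gene the pooled SD of the difference was 0.68 log2 units. This technical spread, which covers only probe sets that had passed the 2-fold limit, was the only error the arrays gave, and the number of arrays limits the precision.

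With 1 array per group no test was run. A gene counted as higher or lower when its log2 difference was at least 1 in size and the higher of its values was at or above the floor, the median of all values on both arrays, 5.75; 786 genes lay under the floor on both arrays. The named genes were Tbx4, the 15 genes with the largest difference each way among those at or above the floor, without predicted gene models, small RNAs, olfactory and vomeronasal receptors and antigen receptor segments, up to 4 members with the largest difference at or above the floor from each gene list, and the reference and sex-linked genes. Gene lists, groups, this rule and all alternatives except 1 were fixed before the data were examined. Where a count of 5 or fewer fell outside the rule, or Has2 and Cemip were singled out, the genes were named after their values were seen, as the text says. Counts of list members take every listed member by the sign of its difference, whatever its level, and the text says how many lay at or above the floor on at least 1 array where some did not and the list stood apart.

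There were 30 gene lists with 848 members, covering matrix, contractile, mural, lung fibroblast, transcription factor, Hox, signalling, inflammatory, metabolic and cell cycle genes and markers of other cell types. For each of the 23 lists with at least 5 listed members, the median difference was given with its percentile among 10000 random lists of the same size, matched in 20 bins of mean value and drawn from the 2639 listed genes. A list was said to stand apart under a percentile of 2.5 or over 97.5, as a description of these arrays. The 95% interval of a median was taken from binomial order statistics and covers the spread between member genes only. Medians and intervals rest on listed members alone, so probe sets with differences under 1 in size enter neither. In simulated lists drawn from the 2639 genes, 100 for each size of 5, 10 and 25 genes, 4%, 4% and 2% of lists with no shift stood apart, as did 45%, 29% and 45% of lists shifted by 1 log2 unit and 92%, 99% and 100% of lists shifted by 3. These lists were random draws, so a share near 5% without a shift was built in and does not cover lists of co-expressed genes. The shifts also gave differences between -1 and 1, which the table does not hold for single probe sets.

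The alternatives were centring each array on its median, quantile normalization, removal of a loess trend of the difference on the mean with a span of 0.4, the probe set of highest mean in place of the mean, probe sets with several symbols assigned to their first, no floor or one at the 75th percentile of values, a 1.5-fold or 4-fold limit, only list members with a mean value at or above the floor, the mean in place of the median, random lists not matched on mean value, and an offset of 16 added on the linear scale. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.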

Results

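The data compared cultured mouse lung fibroblasts that carried the red fluorescent protein tdTomato with those that did not. The mice expressed Cre recombinase under control of Tbx4, a T-box transcription factor of lung and hindlimb mesenchyme, so that cells which had expressed Tbx4 at any earlier time, and their descendants, carried the protein for good. Cultures were separated by flow cytometry into positive cells, called Tbx4-Tm+ here, and negative cells, called Tbx4-Tm-, and RNA of each was hybridized to 1 Affymetrix array. With 1 array per group there was no replicate and no replicate check, so no p-value was computed and each difference describes these 2 arrays. The table used here held 4144 probe sets with log2 values from 1.81 to 12.58, with a median of 5.53 on the Tbx4-Tm+ array and 5.99 on the Tbx4-Tm- array. Every probe set in it differed by at least 1 log2 unit between the arrays, so genes with smaller differences were not analysed here. All differences are given as Tbx4-Tm+ minus Tbx4-Tm-, and the SD of the difference between probe sets of one gene was 0.68 log2 units.

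Tbx4, the gene behind the label, was 2.94-fold higher on the Tbx4-Tm+ array, at 7.04 against 5.48. The largest differences in favour of Tbx4-Tm+ were moderate. They were led by Mrpl44, a mitochondrial ribosomal protein gene, at 3.53, Ccdc85a at 3.28, Sorbs2, which encodes an adaptor of the actin cytoskeleton, at 3.13, and Ttll11 at 3.06. Others were Gzme at 2.84, read only by a probe set that may bind related genes, C1ql3 at 2.62, Ankrd40 at 2.58, Megf10 at 2.56, the mesenchymal transcription factor gene Foxf2 at 2.56 and Slc35f1 at 2.47. The order rests partly on dim values: with an offset of 16 on the linear scale Mrpl44 stood at 3.43, but Sorbs2 at 2.17 and C1ql3 at 1.68, both below Foxf2 at 2.20, and Ccdc85a below Sorbs2. The ceruloplasmin gene Cp reached 2.44, the urea transporter gene Slc14a1 2.39, the sphingosine-1-phosphate receptor gene S1pr3 2.35, the noncoding RNA Snhg18 2.35 and the atypical cadherin gene Fat4 2.34. Differences in favour of Tbx4-Tm- were far larger, and many lay in genes of blood-derived cells. Sash3, an adaptor of lymphoid and myeloid cells, stood at -7.27 in Tbx4-Tm+, next to the complement gene C1qc at -7.21, the chemokine gene Ccl3 at -7.10, the macrophage elastase gene Mmp12 at -7.10 and Cd244a at -6.92. These too have no firm order, since with the offset Mmp12 and C1qc, at -6.28 and -6.24, lay below Sash3 at -5.79. Anpep, which encodes aminopeptidase N, stood at -6.86, the platelet factor gene Pf4 at -6.75, Ccl6 at -6.69, the leukocyte plastin gene Lcp1 at -6.60, C1qb at -6.54, Clec4d, with a probe set that may bind related genes, at -6.53, the cathepsin S gene Ctss at -6.50, Cd48 at -6.38, Ms4a6d at -6.31 and Ccl12 at -6.30.

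By the fixed rule of a 2-fold difference and a higher value at or above 5.75, the median of all values, 884 genes were higher and 960 lower in Tbx4-Tm+, 47.9% of them higher. Scaling changed that split. Centring each array on its median gave 957 higher and 574 lower genes, 62.5% higher, quantile normalization 957 and 570, 62.7% higher, and removal of a loess trend 953 and 635, 60.0% higher. These scalings moved the median difference of all genes up by 0.47, 0.50 and 0.44 log2 units, and all are distorted by the missing smaller differences. Of the 50 lower named genes, 7 fell under the 2-fold limit after centring, and the same 7 after quantile normalization. They were Mcm5 at -0.76 after centring, Mcm7 at -0.54, Tnni2 at -0.65, Mbp at -0.74, Id2 at -0.85, Ifi27l2a at -0.97 and Sesn1 at -0.98, and all but Id2 and Ifi27l2a also fell under it without the loess trend. Quantile normalization left Crip1 at -1.08 and Hspb1 at 1.90. With an offset of 16 on the linear scale 7 named genes, Mcm7, Mbp, Tnni2, Eda2r, Nsdhl, Efemp1 and Des, fell under the limit, and Tbx3 stood at 1.04, Vegfc at 1.09 and Fgf5 at -1.86.

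**Figure D1:**
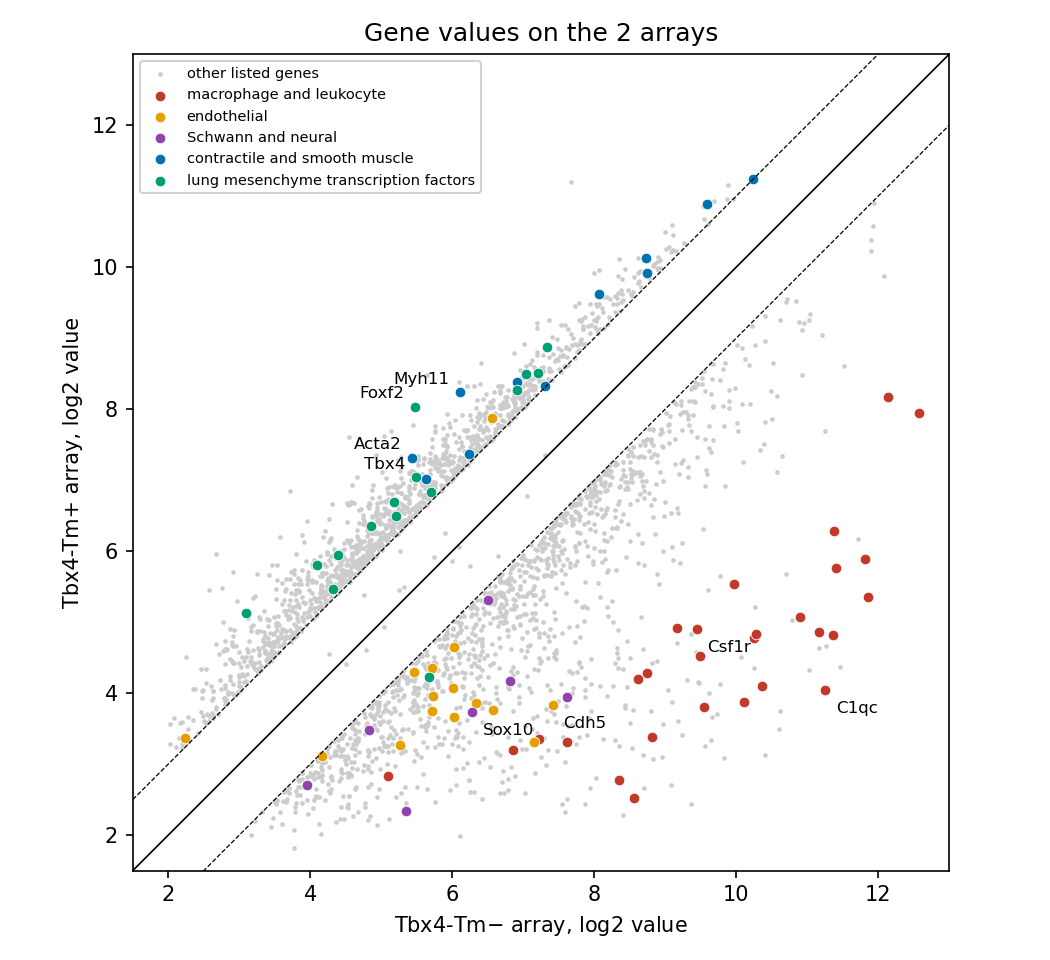
Each point is a gene, with its log2 value on the Tbx4-Tm- array on the x axis and on the Tbx4-Tm+ array on the y axis; colours mark 5 gene lists, the solid line equal values and the dashed lines a difference of 1 log2 unit. The 28 macrophage and leukocyte genes lie below the lower line, most of them far to the lower right. The 11 contractile genes lie above the upper line or on it.

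The macrophage and leukocyte list had the largest difference of all lists. All 28 of its listed members, out of 41, were lower in Tbx4-Tm+, 27 of them at or above 5.75 on at least 1 array, with a median of -5.44 (95% interval -5.83 to -4.45), below every random list. That is 43.5-fold as listed, but the background of the arrays is unknown, only 5 of the 28 reached 5.75 on the Tbx4-Tm+ array, and with an offset of 16 the median was -4.39. The complement genes C1qc and C1qb stood at 11.25 and 11.36 on the Tbx4-Tm- array against 4.04 and 4.82, Ctss at 11.85 against 5.35, and Mpeg1, which encodes a pore-forming protein of macrophages, at 11.16 against 4.87. The chemokine and inflammatory cytokine list was also lower as a group, with 13 of 18 listed members out of 39 lower, 10 of them at or above 5.75. The median was -1.74 (-4.40 to 1.18), at percentile 0.28, but -1.27 after centring and -1.11 after quantile normalization. Ccl3, Ccl6, Ccl4 and Ccl9 differed by -7.10, -6.69, -5.22 and -5.13. Its 5 higher members, named after their values were seen, were Il11 at 2.11, Il6 at 1.31, Tslp at 1.26, Ptgs2 at 1.19 and Cxcl12 at 1.18, of which Tslp lay under 5.75 on both arrays. The endothelial and Schwann lists were lower as well. The endothelial list had 13 of 15 listed members out of 28 lower, but only 7 of these were at or above 5.75 on at least 1 array. The median was -1.93 (-2.47 to -1.16), at percentile 0.26, but -1.14 with the offset of 16. Lower members included the endothelial cadherin gene Cdh5 at -3.59, Emcn at -3.84, Lyve1 at -2.81 and Pecam1 at -2.47. Flt4 and Prox1, named after their values were seen, differed by 1.32 and 1.14, the latter under 5.75 on both arrays. All 7 listed members of the Schwann and neural list, out of 22, were lower, 4 of them at or above 5.75. The median was -2.55 (-3.67 to -1.20), at percentile 0.21, but -1.43 with the offset of 16. Among those at or above 5.75 the largest differences were those of the nerve growth factor receptor gene Ngfr at -3.67, the neural cell adhesion gene L1cam at -2.64 and the neural crest transcription factor gene Sox10 at -2.55. Restricted to members with a mean value of at least 5.75, the endothelial and Schwann lists had too few members for a median.

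Most listed genes for mesenchymal transcription factors were higher in Tbx4-Tm+, while on the same arrays the macrophage list was lower at a median of -5.44. Of the lung mesenchyme transcription factor list, 15 of 28 members were listed and 14 of these were higher, 12 of them at or above 5.75. The median was 1.5 (1.29 to 1.56), at percentile 99.99. Foxf2 stood at 8.03 against 5.47, and the T-box genes Tbx5 and Tbx3 were higher by 1.72 and 1.56, the first over 2 probe sets at 1.10 and 2.33. Twist1, named after its value was seen, was the lower member at -1.44 and lay under 5.75 on both arrays. All 7 listed Hox genes, out of 34 genes of positional identity, were higher, 6 of them at or above 5.75. The median was 1.5 (1.12 to 1.70), at percentile 99.79. The largest differences were those of Hoxa3 at 1.70, Hoxb5 at 1.55, Hoxb4 at 1.52 and Hoxb6 at 6.68 against 5.18. Both lists share 4 genes, Hoxa4, Hoxa5, Hoxb5 and Hoxb6, so they are not independent.

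The listed contractile genes were higher in Tbx4-Tm+ as well, beside the macrophage list, at a median of -5.44. Of the contractile and smooth muscle list, 11 of 23 members were listed and all 11 were higher and at or above 5.75. The median was 1.39 (1.02 to 1.88), at percentile 99.88. Smooth muscle myosin heavy chain Myh11 stood at 8.24 against 6.11, smooth muscle actin Acta2 at 7.32 against 5.43, the integrin gene Itga8 at 9.62 against 8.07 and the tropomyosin gene Tpm1 at 8.38 against 6.92. The lipofibroblast and alveolar fibroblast list had 6 of 7 listed members out of 19 higher, 4 of them at or above 5.75. The median was 1.51 (-1.73 to 1.94), at percentile 99.57. Its higher members were led by Limch1 at 1.94, the platelet-derived growth factor receptor gene Pdgfra at 7.85 against 6.04 and the nephronectin gene Npnt at 1.60, with the lipoprotein lipase gene Lpl lower at -1.73. With each gene read from its probe set of highest mean, that list had a median of 1.22 at a percentile of 92.2 and no longer stood apart. The pericyte and mural list had 4 of 6 listed members out of 17 higher. The median was 1.23, at percentile 92.1, but the mean was -0.33 and the median with the offset 0.49. Its members included the guanylate cyclase subunit genes Gucy1b1 at 2.20 and Gucy1a1 at 1.70 against Anpep at -6.86 and Postn at -1.47, while Notch3 at 1.37 and Trpc6 at 1.10, named after their values were seen, lay under 5.75 on both arrays. Of the adventitial fibroblast list, 3 of 5 listed members out of 23 were higher, with a median of 1.07, a percentile of 64.9, a mean of -0.02 and a median of 0.52 with the offset. Among them Pdgfra was 3.49-fold and Mfap5 2.29-fold higher and Col14a1 was lower at -1.71; Ebf1 at 1.07 and Cd34 at -2.47, named after their values were seen, lay under 5.75 on both arrays.

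Most listed genes of bone morphogenetic protein, growth factor and Wnt signalling were higher in Tbx4-Tm+, again beside the macrophage list, at a median of -5.44. In the bone morphogenetic protein list, 10 of 29 members were listed and 9 of these were higher, 8 of them at or above 5.75. The median was 1.44 (1.14 to 1.88), at percentile 99.86. The antagonist genes Fst and Fstl3 stood at 1.91 and 1.44, the receptor gene Bmpr1b at 1.88 and the ligand gene Bmp5 at 1.69, while Id2 was lower at -1.31. Of the list of growth factors, their receptors and binding proteins, which spans the fibroblast, platelet-derived, insulin-like, vascular endothelial, epidermal, hepatocyte and nerve growth factor families, 17 of 38 members were listed and 13 of these were higher, all 13 at or above 5.75. The median was 1.35 (1.04 to 1.51), at percentile 99.76, and the mean 0.70. Members included Pdgfra at 7.85 against 6.04, Vegfc at 1.63 and the epiregulin gene Ereg at 1.59. Fgf5 was lower at -2.82, as were Pdgfb at -1.31, Igfbp3 at -1.30 and Pdgfc at -1.12, these last 3 named after their values were seen and Pdgfb under 5.75 on both arrays. The Wnt list had 12 of 15 listed members out of 44 higher, 10 of them at or above 5.75. The median was 1.29 (1.12 to 1.52), at percentile 98.8, and the mean 0.85. Members included the Wnt antagonist gene Sfrp1 at 1.62 and the receptor genes Ryk at 1.52, Fzd1 at 1.49 and Fzd4 at 1.48. Its lower members, named after their values were seen, were Lgr6 at -1.72, Rspo1 at -1.43 and Fzd6 at -1.14, of which Lgr6 and Rspo1 lay under 5.75 on both arrays. Restricted to members with a mean value of at least 5.75, the Wnt list had a median of 1.29 at a percentile of 96.2 and no longer stood apart. The transforming growth factor beta list did not stand apart, with 6 of 9 listed members out of 30 higher, a median of 1.03, a percentile of 60.9 and a mean of 0.01. Its target gene Tgfbi was lower at -4.76, Id2 at -1.31 and, named after its value was seen, Tgfbr1 at -1.15, while Ltbp1 and Tgfb3 were higher by 1.58 and 1.30.

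Listed matrix genes were mixed, beside the macrophage list, at a median of -5.44. Of the fibrillar collagen and interstitial matrix list, 9 of 11 listed members out of 33 were higher. The median was 1.20, at percentile 92.9. The versican gene Vcan stood at 8.91 against 7.01 and Col12a1 at 7.71 against 6.16, whereas Col14a1 and the periostin gene Postn were lower at -1.71 and -1.47. The basement membrane list had 7 of 10 listed members out of 24 higher. The median was 1.05, at percentile 71.4, but 1.61 after quantile normalization, and the mean was 0.41. Differences were split, with Col4a5 at 1.70 and Npnt at 1.60 against Col18a1 at -2.20, the perlecan gene Hspg2 at -1.53 and, named after its value was seen, Agrn at -1.06. Among matrix remodelling enzymes, 9 of 12 listed members out of 40 were higher. The median was 1.21, at percentile 96.9, but the mean was 0.25, at percentile 89.8. The protease gene Adamts1 stood at 1.76, the prolyl hydroxylase subunit gene P4ha2 at 1.51 and the collagenase gene Mmp8 at 10.50 against 8.99. Mmp12 was lower at -7.10, as were Plau and Plod1, named after their values were seen, both at -1.08. Of the genes of hyaluronan synthesis and binding, 3 of 7 listed members out of 23 were higher and 4 lower. The median was -1.67, at percentile 7.33, but the mean was -0.71, at percentile 43.5, and the median of members with a mean value of at least 5.75 was -0.13, at percentile 50.9. The lower ones were the receptor genes Stab1 at -3.68, Lyve1 at -2.81, Tlr2 at -1.71 and Tlr4 at -1.67, whereas Vcan, the synthase gene Has2 and Cemip were higher by 1.90, 1.58 and 1.41; Tlr4, Has2 and Cemip were named after their values were seen.

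**Figure D2:**
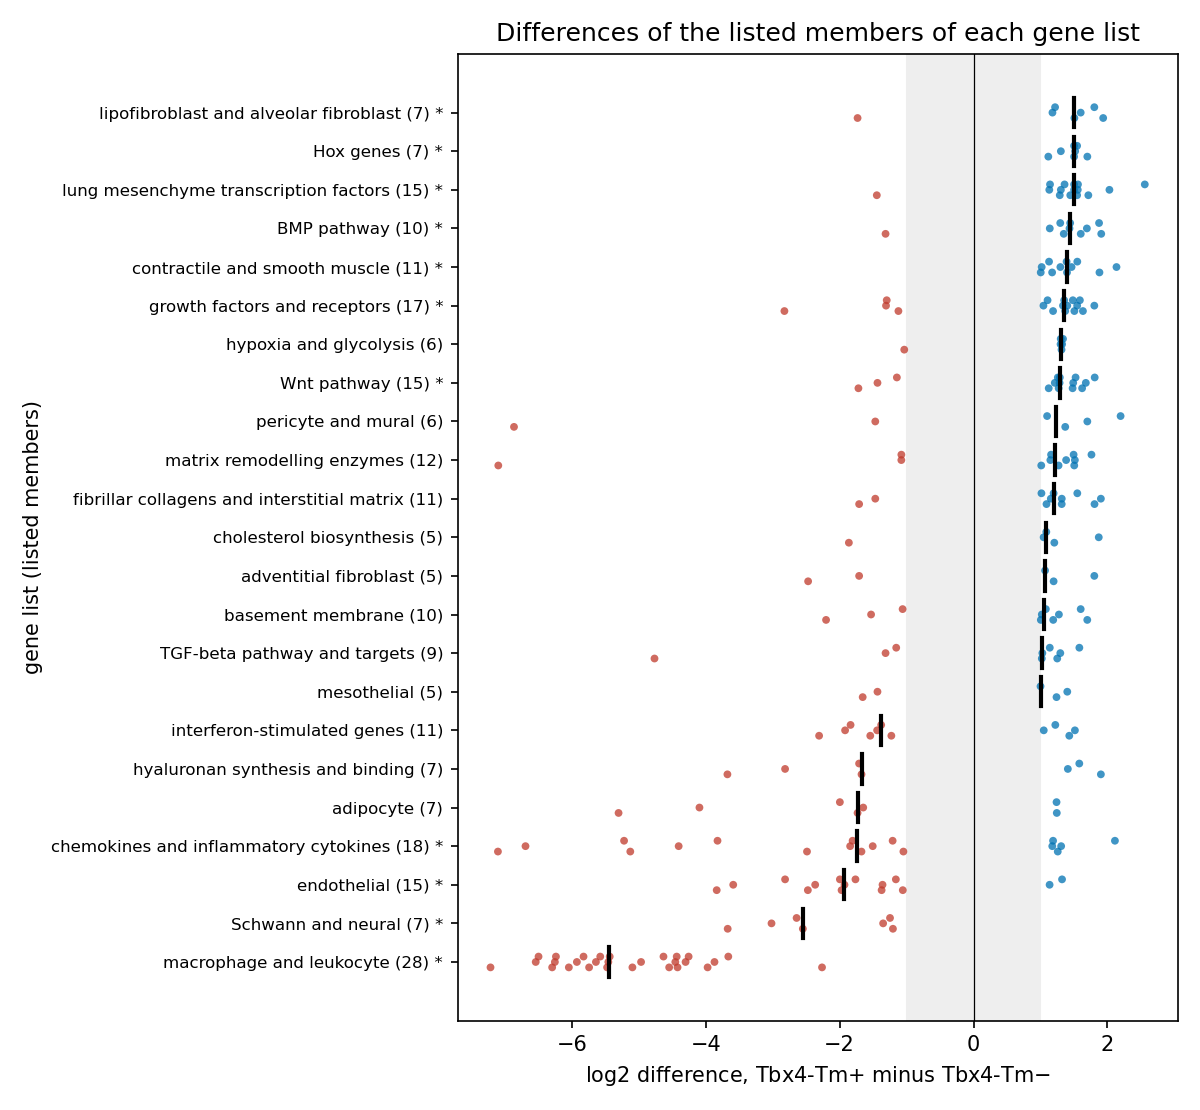
Each point is the log2 difference, Tbx4-Tm+ minus Tbx4-Tm-, of a listed member of the gene list named on the y axis, with the number of listed members in brackets, a black bar at the median, blue for higher, red for lower and an asterisk where the list stood apart. The grey band from -1 to 1 is the range that the table does not hold for single probe sets, and medians run from -5.44 for the macrophage and leukocyte list to 1.51 for the lipofibroblast and alveolar fibroblast list.

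Metabolic, interferon and mesothelial lists did not stand apart. The adipocyte list had 5 of 7 listed members out of 24 lower. The median was -1.73, at percentile 3.83. At or above 5.75 the lower members were the fatty acid receptor gene Cd36 at -5.30, Cebpa at -4.09, Lpl at -1.73 and Fabp4 at -1.65, beside the macrophage list, at a median of -5.44. Lep, at 2.55 against 4.55, was lower too and lay under 5.75 on both arrays, and Scd1 and Dgat2 both differed by 1.24, the latter under 5.75 on both arrays; these 3 were named after their values were seen. On the same arrays interferon-stimulated genes were lower in 7 of 11 listed members out of 34, 5 of them at or above 5.75. The median was -1.38, at percentile 7.06, but -0.91 after centring, and the mean was -0.58, at percentile 28.5. Differences were split here too, with Trim30a at -2.31, Oas1a at -1.92 and Ifi27l2a at -1.44 against Ifit1 at 1.51. Of 3 more genes named after their values were seen, Irgm1 was higher by 1.22, while Iigp1 at 1.43 and Mx2 at 1.05 lay under 5.75 on both arrays. Of the hypoxia and glycolysis list, 5 of 6 listed members out of 28 were higher. The median was 1.31, at percentile 97.0. Members included Vegfa at 1.34, Egln3 at 1.32, Ndrg1 at 1.31 and the adrenomedullin gene Adm at 1.30, as well as Pdk1 at 1.30, under 5.75 on both arrays, and Pfkp at -1.03, both named after their values were seen. The cholesterol biosynthesis list had 4 of 5 listed members out of 25 higher. The median was 1.09, at percentile 63.2, and the mean 0.67, with Sc5d at 1.87, Hsd17b7 at 1.21, Nsdhl at 1.09 and, named after its value was seen, Cyp51 at 1.05, and with the squalene synthase gene Fdft1 lower at -1.86. The mesothelial list had 3 of 5 listed members out of 24 higher. The median was 1.0, at percentile 53, but the mean was 0.11, with Igfbp5 at 1.40, Hspb1 at 1.24 and Efemp1 at 8.72 against 7.72, against Crip1 at -1.66 and Rspo1 at -1.43, the latter under 5.75 on both arrays.

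Lists with fewer than 5 listed members were given no median. Of 40 cell cycle genes 2 were listed, the helicase genes Mcm5 at -1.22 and Mcm7 at -1.01, both under the 2-fold limit after each of the 3 scalings. Of the p53 and senescence list, Btg2 and Eda2r were higher by 1.21 and 1.19 and Sesn1 was lower at -1.45. The cartilage and bone list had the osteoglycin gene Ogn at 2.06, Fmod at 1.38 and Sox5 at 1.22, and the epithelial list Aqp5 at -1.56, Napsa at -1.35 and Hopx at -1.18. Of the skeletal and cardiac muscle list, Acta1 stood at 1.73, Pax3 at 1.47 and the desmin gene Des at 1.02, with Tnni2 at -1.11. Fmod, Sox5, Napsa, Hopx and Pax3 were named after their values were seen and lay under 5.75 on both arrays. The checks held the Y-linked gene Eif2s3y, at 3.18 against 4.44 and so under 5.75 on both arrays, and 2 of 20 reference genes, Gusb at -2.11 and Ywhaz at 1.37.

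Members not listed were not analysed here. Of the 23 lists with at least 5 listed members, 11 stood apart from random lists, 7 toward higher and 4 toward lower values in Tbx4-Tm+. Chance would give 1.15 if genes differed independently of each other. Genes expressed by the same cells need not, and some lists share members, such as Pdgfra in the lipofibroblast and growth factor lists. The 11 lists are thus not separate results. The random lists were drawn from genes whose probe sets had all differed by 2-fold or more, so a percentile compares a list with other differing genes and not with the whole array.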

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

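The test of a scaling difference was chosen after the result was seen, and so was the comparison with other lower genes beside the second test. The 21 bacterial control probe sets, which read RNA added during preparation and no mouse gene and entered no comparison, were all lower in Tbx4-Tm+, with a median of -1.78 and a range of -3.16 to -1.25, a 3.43-fold difference at the median. A scaling offset of that size would have left nearly all other probe sets lower as well, but 46.1% of them were higher, which argues against it. More control RNA relative to sample RNA on the Tbx4-Tm- array stays open. The SD of the control sets was 0.85 of that between probe sets of genes agreeing in direction (0.51 over 0.60). For lower genes the SD of gene means over that between their lower probe sets was 1.63, a ratio of another kind. The 21 control sets read only 4 transcripts and the 2-fold limit narrows their spread, so the ratio of 0.85 decides nothing. That weakness was found after the ratio was seen, and no biological explanation was tested.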

How the results depend on the processing

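The setting that left out the 50 listed macrophage, endothelial and Schwann genes was chosen after the data were seen; it gave 883 higher and 922 lower genes. The count of lower genes, 960 as reported, was 574 after centring, 570 after quantile normalization and 635 without the loess trend. A floor at the 75th percentile left 426 higher and 571 lower genes and a 4-fold limit 41 and 373, both by construction. Of the 11 lists that stood apart, 7 did so under all 9 alternatives run on lists, of which centring, a shift shared by all genes, could not change a percentile, and the endothelial and Schwann lists under all but the restriction to members at or above the floor, which left them too few members. The lipofibroblast list did not with the probe set of highest mean, with a median of 1.22 at a percentile of 92.2, nor the Wnt list with members at or above the floor, with a median of 1.29 at 96.2. Matrix remodelling enzymes stood apart after quantile normalization (1.76), without the loess trend (1.54), with the probe set of highest mean (1.22) and with the offset of 16 (1.19), hypoxia and adipocyte genes with the probe set of highest mean (1.38 and -1.86), and interstitial matrix by the mean of its members (0.83). Medians of lists that did not stand apart left their interval after centring for transforming growth factor beta (1.49), matrix remodelling (1.68), hypoxia (1.77) and mesothelial genes (1.47), after quantile normalization for basement membrane (1.61), transforming growth factor beta (1.51), matrix remodelling (1.76), hypoxia (1.79) and mesothelial genes (1.47), and without the loess trend for transforming growth factor beta (1.42), matrix remodelling (1.54) and hypoxia genes (1.59), the last also with the probe set of highest mean. Lists that stood apart left theirs too, upward under all 3 scalings for transcription factors, Hox, growth factors and Wnt (1.65 to 1.97), under centring and quantile normalization for lipofibroblast and bone morphogenetic protein genes (1.90 to 1.97) and under quantile normalization for contractile genes (1.93), toward 0 with the offset for transcription factors (1.17), endothelial (-1.14) and macrophage genes (-4.39), and by the mean of members for Wnt (0.85) and growth factors (0.70). The scalings moved the median of all genes up, since the Tbx4-Tm+ array had the lower median; the cause of the other shifts was not tested. Of the 117 named genes, 32 moved by more than the SD between probe sets with the offset, all toward 0, 6 with the probe set of highest mean and 4 after quantile normalization; centring, which moves every gene alike, and the several-symbol setting, which left 116 as they were, test nothing here. With members at or above the floor, 7 of the 23 lists, endothelial and Schwann included, had too few members for a value. Leaving out an array was not possible with 1 per group. No paired analysis was possible because each group had 1 array and no test was run. Signal over background is unknown, so differences of dim genes rest on values that hold an unknown share of signal.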

Other observations

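The tests of macrophages, of scaling and of the lower fibroblast genes were chosen after the results were seen, as were the gene groups in the next paragraphs, the comparison with other higher genes and the reasons for which a test decides nothing; the tests of the SD of higher fibroblast genes and of neighbouring genes were chosen before. All 10 listed genes of cyclic nucleotide signalling, out of 14 looked up, were higher in Tbx4-Tm+, with a median of 1.62, but 3 of them, Pde5a, Prkg2 and Pde10a, lay under 5.75 on both arrays. The other 7 included the guanylate cyclase subunit gene Gucy1b1 at 2.20 and the natriuretic peptide receptor gene Npr3 at 1.62. Of 30 axon guidance genes, 22 were listed, 15 higher and 7 lower, 10 and 4 of them at or above 5.75, with a median of 1.28. Sema5a, Sema3a and Efna5 were higher by 2.21, 2.05 and 2.05 and the receptor gene Robo1 by 1.73, whereas Plxnc1 and Sema4d were lower at -4.45 and -3.99. A prostaglandin group had 5 listed members, out of 11 looked up. The synthase genes Ptges and Ptgs2 and the receptor gene Ptger2 were higher by 2.24, 1.19 and 2.15, and Hpgds was lower at -3.49. The group also held Alox5ap, lower at -5.62, which encodes a lipoxygenase-activating protein of leukotriene synthesis and is not a prostaglandin gene.

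Most listed genes of a lysosomal and a pattern recognition group were lower in Tbx4-Tm+, beside the macrophage list, at a median of -5.44. Of 18 lysosomal hydrolase genes looked up, 14 were listed and 13 of these lower, with a median of -1.73, including Ctss at -6.50, Ctsh at -3.87 and Acp5 at -2.97, while Ctsf was higher by 1.17. All 12 listed pattern recognition receptor genes, out of 16 looked up, were lower, 11 of them at or above 5.75, with a median of -3.52, including Clec4n at -6.02, Clec5a at -5.11 and Tlr13 at -4.92. These groups were put together from the differences themselves and are no independent evidence of a direction.

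The 28 listed macrophage genes were all lower in Tbx4-Tm+, with a median of -5.44. The median nearest to 0 after centring or quantile normalization was -4.95. Those scalings moved the median of all genes by just 0.47 and 0.50, so this value could hardly differ and decides nothing about scaling. A scaling offset as large as the list's median would have left nearly all probe sets lower, but 45.9% of them were higher, which argues against it. Macrophages among the sorted Tbx4-Tm- cells stay open: the list's median of 10.04 on that array, with Lyz2 at 12.58 and Ctss at 11.85, lay at percentile 97.46 of the 2639 listed genes, but a difference of that size alone would put it at percentile 87.2 with a Tbx4-Tm+ median at the 5th percentile of genes, and at 72.6 with one at the lowest value of any gene. Under 75 the level would have counted against macrophages, so whether it speaks for them turns on which of these bounds is taken, and the first was chosen after both were seen. No other fixed list held any of the 28, but that was set when the lists were written and does not show which cells made the transcripts. The lysosomal group put together later does hold Ctss. A sort on tdTomato alone would leave macrophages among negative cells, while no step against blood-derived cells is named in the labels. Expression of these genes by Tbx4-Tm- fibroblasts themselves was not tested and stays open.

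Fibroblast genes were mostly higher in Tbx4-Tm+, which dilution of fibroblast RNA by other cells on the Tbx4-Tm- array could produce if other cells gave 62.6% of its RNA at the median of the higher genes, or 72.9% after centring, shares that rest on genes past the 2-fold limit and picked for being higher. Dilution alone leaves no fibroblast gene lower in Tbx4-Tm+, but 3 of 26 listed interstitial matrix and transcription factor genes, Col14a1, Postn and Twist1, were lower, though just 1 of them, Postn, lay above 5.75 by more than the SD between probe sets. Over all 4 lists named next, 4 of 44 were lower and 2 lay that far above 5.75, Postn and Lpl at 8.01 against 6.28, which reaches the number set, for the first 2 lists, to count against dilution, but other cells could have brought these transcripts, the adipocyte list also holds Lpl, and this was not tested, so the lower genes leave dilution open. For the 40 higher genes of the interstitial matrix, transcription factor, contractile and lipofibroblast lists dilution cannot be told apart from a difference between cells. The SD between genes was 0.69 of that between probe sets of the 14 with several (0.34 over 0.50), under 1 as dilution needs. Yet all other higher genes gave 0.94, also under 1, and the 2-fold limit narrows these spreads, so the ratio decides nothing. Listed were 11 of 33 interstitial matrix, 15 of 28 transcription factor, 11 of 23 contractile and 7 of 19 lipofibroblast genes. Dilution by 62.6% would also move unlisted members that only fibroblasts express past the limit. The table does not show why a gene is missing, so unlisted members were not weighed. A difference between fibroblasts of the Tbx4 lineage and others stays open and was not tested.

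A separate hypothesis for neighbouring genes was that adjacent genes differ in the same direction more often than random pairs. Among 343 adjacent pairs of protein-coding genes whose symbols begin differently, 62.1% had the same direction, against a median of 50.1% with shuffled directions, whose central 95% ended at 55.4%; the observed share lay at percentile 100. Over all 397 adjacent pairs the share was 66.0%. Genes of the same cell type that lie side by side may account for part of this excess, which was not tested.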
